A study of Homo sapiens with 28 samples.

How the data were processed

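RNA was measured by sequencing in 28 libraries of primary human blood cells. Per the labels' protocols, all came from apheresis buffy coat (the white-cell layer of collected blood) and held mononuclear cells. The labels give 3 groups: 11 libraries of acute myeloid leukaemia (AML), 10 labelled bcCML and 7 labelled BM. The series' design names AML, bcCML and healthy specimens, so BM is the healthy baseline by elimination; the label is not spelled out. Libraries are named here by group and by the number in their label. The labels call them separate samples and do not state the donors, so p-values measure the spread between these samples.

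Per the labels' protocols, polyadenylated RNA was made into strand-marking libraries with random priming, and single-end reads of 100 bases were produced. Per the submitters' processing notes, fastp 0.20.1, STAR 2.7.6a, Subread 2.0.1 and featureCounts were used with genome build hg38. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes on opposite strands may therefore share a count, and near-identical copies, such as HBA1 with HBA2 or HSPA1A with HSPA1B, are uncertain as single genes.

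The authors deposited 1 table of whole-number counts per gene symbol, not normalised, with 59471 gene rows and a column per library. In it 21984 genes had 0 counts in every library. Totals ranged from 7658430 to 14726597 counts per library. No pair of libraries within a group agreed within sampling noise: the closest pair had a chi-square of 11.5 per degree of freedom. Within bcCML, replicates 4 and 10 were the most alike, with a correlation of log2 CPM of 0.966 against a median of 0.843 over the group's pairs. Their chi-square of 30.2 speaks against copied counts, not against a shared donor. They were counted as separate samples throughout. XIST, TSIX and Y-linked genes (520 in the table) stayed in the library totals and were left out of every test. Positions are from GENCODE release 29 on GRCh38, matched by symbol, with a single locus for 15426 of the 15997 genes tested.

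Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM, and fitted with the robust quasi-likelihood model over all 28 libraries, so that the 3 groups shared an estimate of the spread. The contrasts were AML versus BM, bcCML versus BM and bcCML versus AML, each two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are ratios of fitted mean counts and come with a standard error (SE); CPM, counts scaled to the same total in every library, were computed from the deposited counts, and log2 CPM used a prior count of 2. A fold change follows the mean count, so a library with a very high count weighs more in it than in a mean of log2 CPM. Intervals for ratios of very low counts are exact, at 95%, and cover counting error only.

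All designs, gene lists and alternatives were fixed before the data were examined. The 26 lists cover stem and progenitor genes, the 17-gene stemness score, the HOXA and HOXB cluster, leukaemia-associated antigens, primary granule, secondary and tertiary granule, mature neutrophil, monocyte and macrophage, dendritic cell, eosinophil with basophil and mast cell, erythroid, megakaryocyte and platelet, T cell, natural killer and cytotoxic, B precursor, mature B cell, plasma cell, marrow stroma and endothelium, proliferation, interferon response, immediate early and stress, JAK-STAT and RAS-MAPK feedback, p53 target, MHC class II and mitochondrially encoded genes. The remaining list, called oncogene cooperation, was meant to hold genes that respond synergistically to cooperating oncogenes, and is partial. All lists, the 17-gene score included, were written from general knowledge and not compared with a published source. Some genes stand in more than 1 list.

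Lists were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation of 0.01, adjusted over the lists of a comparison. The result with an estimated correlation is given beside it. A score per library, the mean log2 CPM of a list's tested members, was compared between groups by a two-sided exact permutation test against BM, and by a permutation test with 100000 resamples between AML and bcCML (scipy 1.17.1), adjusted over the lists. A count of libraries above or below refers to the median of the second group. The convention for counting both tails in these permutations was set after first values had been seen. Named genes were, per comparison, the 5 largest changes in each direction past the threshold with a mean log2 CPM of at least 4 in the higher group and at least 80% of the first group's libraries on the called side of the second group's median; the member of each list with the smallest adjusted p; and 12 fixed markers. Not every gene so named is reported here. Other list members given as examples were chosen after their values were seen.

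Both leukaemias were compared with the same BM libraries. Overlaps were therefore set beside simulated unchanged groups, with BM drawn anew so that its sampling error entered both comparisons (added after seeing the data), beside the product of the 2 counts of calls divided by the genes tested, and beside 10 splits of the BM libraries into 4 and 3. Alternatives were DESeq2 size factors in edgeR, library totals alone, no filter, a stricter filter (at least 10 CPM in at least 7 libraries), the DESeq2 1.42.0 test, limma voom with quality weights, fits of only the groups compared, the replicate number as a block, haemoglobin genes left out, a test against a log2 fold change of 1, each library left out in turn, and median scores or a prior count of 0.5 for list scores.

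The gene test was tested on simulated data with 50 genes changed per fold size among 15997. Each gene was given the same spread in all 3 simulated groups. The real groups differed in spread, so the recovered shares need not hold for them. For AML versus BM it recovered 34% of 2-fold, 70% of 4-fold, 88% of 8-fold and 92% of 16-fold changes. For bcCML versus BM the shares were 32%, 62%, 78% and 86%, and for bcCML versus AML they were 36%, 78%, 86% and 92%. The labels give no sequencing batch. Details of the donors and of each collection are not given in the sources used here, so any difference in them between the groups is not separated from the disease. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.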

Results

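The series asks how gene expression in human leukaemia specimens differs from that of healthy specimens, for AML and for bcCML. It holds 28 RNA libraries: 11 of AML, a cancer of myeloid blood precursors, 10 of bcCML and 7 of BM, the baseline. Deposited counts per library ranged from 7658430 to 14726597, and 15997 genes were tested. CD34, a surface protein of blood stem and progenitor cells, stood between 86.2 and 1870 CPM in the 28 libraries, with a median of 536 CPM. PTPRC, the pan-leukocyte phosphatase CD45, lay between 200 and 1080 CPM. Markers of mature cells ranged widely. Medians over the 28 libraries were 1.15 CPM for the T cell receptor component CD3E (0 to 173), 0.634 CPM for the monocyte receptor CD14 (0 to 30.5) and 0.0772 CPM for MS4A1, the B cell protein CD20 (0 to 26.8). They were 144 CPM for LYZ, lysozyme (6.94 to 4900), and 11.8 CPM for HBB, the adult beta globin (0 to 974). In BM alone CD34 stood between 345 and 540 CPM. MPO, of the primary granule list, lay there between 3727 and 22170 CPM, and DNTT, of the B precursor list, between 213.7 and 1679 CPM. CD3E was 1.32 to 4.23 CPM and CD14 0.349 to 5.21 CPM. The baseline was thus rich in precursor transcripts and poor in these T cell and monocyte markers. The labels' protocols name apheresis buffy coat for all libraries, but which cells the BM libraries held is not settled here. Their levels are not to be read as those of unselected healthy blood. Differences from BM may not hold against other blood or marrow cells.

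The BM libraries were alike and the leukaemia libraries were not. The median over genes of the standard deviation of log2 CPM was 0.24 in BM (n = 7), 0.51 in AML (n = 11) and 0.67 in bcCML (n = 10). On the first principal component, which held 31.4% of the variance of the 1000 most variable genes, BM lay at one end and most AML libraries at the other, with bcCML spread between. By mean correlation of log2 CPM, 6 of the 10 bcCML libraries were closest to BM, 2 to AML and 2 to their own group. Of the AML libraries 10 were closest to their own group and replicate 11 to BM (0.83 against 0.793 for AML). A mean correlation falls with the scatter inside a group, so it favours BM. The median correlation of pairs was 0.973 in BM, 0.880 in AML and 0.843 in bcCML. On the first component AML replicate 11 lay at -12.4 and every bcCML library at 39.6 or below, against 58.9 or above in BM. AML replicate 11 stood apart from the other AML libraries and expressed B-lineage genes, with PAX5 (a B cell identity factor) at 777 CPM and MPO (the neutrophil peroxidase) at 6.37 CPM.

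**Figure D1:**
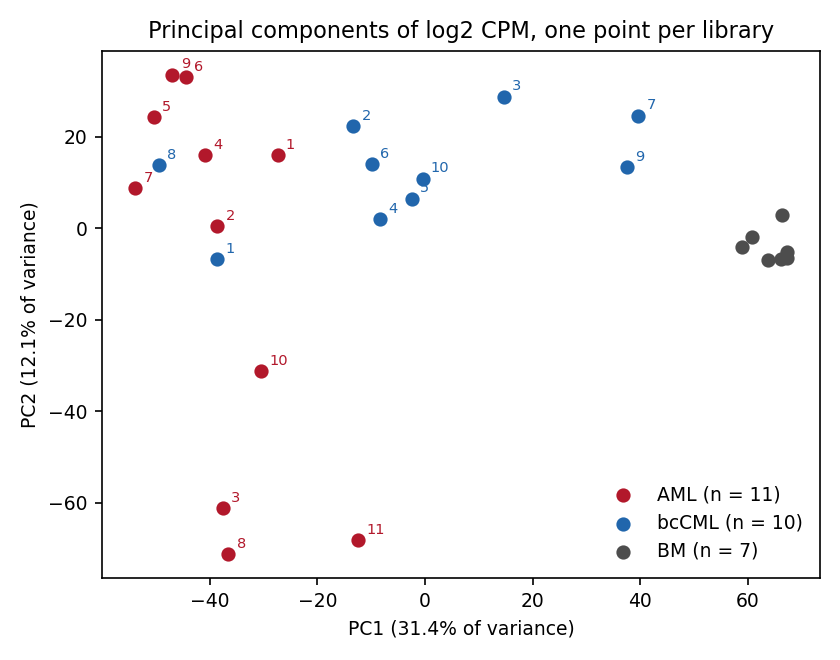
Principal components 1 and 2 of log2 CPM over the 1000 most variable genes, 1 point per library, coloured by group, with the replicate number beside leukaemia libraries. The 7 BM libraries sit together at the right, while AML and bcCML libraries spread over the left and the middle.

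In AML, red-cell and granule transcripts were far lower than in BM, 4 of 18 B precursor genes were lower, and leukaemia antigens and p53 targets were higher. Leaving out AML replicate 11 turned the 4 into 12. The erythroid and the secondary and tertiary granule lists held with an estimated correlation, while primary granule and B precursor genes (each adjusted p = 0.0984 with an estimated correlation), antigens (0.103) and p53 targets (0.16) did not. CA1, an erythroid carbonic anhydrase, had a median of 0 CPM in AML and 86.2 CPM in BM (log2 fold change -10.18 ± 1.40 SE, n = 11 and 7, edgeR adjusted p = 2.94e-05). HBB fell by 8.08 ± 1.12 (SE) on the log2 scale, from a median of 465 CPM in BM to 0.12 CPM in AML. Without AML replicate 2 the change of CA1 was -10.79, and without AML replicate 3 that of HBB was -8.97. WT1, a zinc-finger transcription factor used as a leukaemia marker, rose 20.4-fold (log2 fold change 4.35 ± 0.47 SE, adjusted p = 3.33e-06) and was above the BM median in 11 of 11 AML libraries. In all, 3430 genes changed, 2061 higher and 1369 lower in AML.

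With all libraries in the fit, the erythroid list had the largest share of members lowered among the lists called in AML. Of its 21 tested members 15 fell, 0 rose and 6 did not pass the test, and 17 fell when adjusted over the list alone. AHSP, the chaperone of free alpha globin, fell by 8.24 ± 0.94 (SE). EPB42, a red-cell membrane protein, had 1 count over all AML libraries against 370 in BM, a BM to AML ratio of 618 (95% counting interval 110 to 24500). KLF1 and GATA1, transcription factors of nucleated erythroid precursors, fell by 3.52 ± 0.91 and 2.75 ± 0.96. Without AML replicate 3, which held the EPB42 count, AHSP was -9.50 and KLF1 -4.15. GATA1 was -3.64 without AML replicate 8 and lost its call without any other AML library but replicates 3 and 11, or without any BM library (-2.86 to -2.60). The erythroid score per library was 0.08 ± 0.61 in AML (SD, n = 11) and 4.29 ± 0.75 in BM (SD, n = 7), with every AML library below every BM library (exact permutation, adjusted p = 0.000163, the smallest these permutations give). The list was called by camera (adjusted p = 3.71e-14), and held with adjusted p = 0.0472 with an estimated correlation. Of 16 megakaryocyte and platelet genes 5 fell and 0 rose, among them the platelet chemokine PF4, which fell by 4.13 ± 1.10 (camera adjusted p = 0.00211; adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone the count was also 5.

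Granulocyte genes were lower as well. Of 13 primary granule genes 9 fell and 0 rose, and the count was 9 when adjusted over the list alone (camera adjusted p = 4.71e-08; adjusted p = 0.0984 with an estimated correlation). MS4A3, a marker of granulocyte and monocyte precursors, fell by 7.32 ± 0.97 (SE), and ELANE, neutrophil elastase, by 5.77 ± 1.36. Without AML replicate 10 the first was -8.84, and without AML replicate 1 the second was -7.14. MPO had a log2 fold change of -2.21 ± 1.35 and did not pass the test (adjusted p = 0.244), but passed under limma voom at -6.12. Of 10 secondary and tertiary granule genes 5 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 2.75e-06; adjusted p = 0.0223 with an estimated correlation). LTF, lactoferrin, had 2 counts over all AML libraries and 2050 in BM, a BM to AML ratio of 1710 (95% counting interval 473 to 14100), with both AML counts in replicate 3. In the eosinophil, basophil and mast cell list 7 of 16 fell and 0 rose, both ways of adjusting, including CLC, the Charcot-Leyden crystal protein, by 7.57 ± 0.77 (camera adjusted p = 2.18e-06; adjusted p = 0.0928 with an estimated correlation). The mature neutrophil list was not called (1 rose, 1 fell, adjusted p = 0.516); its median and its test were negative and its mean positive at 0.26. Of its members 0 rose without AML replicate 9 or BM replicates 2, 3, 5, 6 or 7, and 2 without AML replicates 6, 8 or 11 or bcCML replicates 2, 9 or 10.

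Among monocyte and macrophage genes 3 of 15 fell and 1 rose, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.00699; adjusted p = 0.34 with an estimated correlation). LYZ fell by 3.12 ± 0.92 (SE), S100A12, a calcium-binding protein of monocytes and neutrophils, fell by 6.46 ± 1.02, and ITGAM, the CD11b integrin, rose. LYZ was -3.75 without AML replicate 2 and S100A12 -7.36 without AML replicate 10, and ITGAM lost its call without AML replicates 2, 5 or 9 or BM replicates 2 to 6 (1.84 to 2.15). The list had 5 lower members without AML replicate 2 or bcCML replicates 2 or 8, and 6 without AML replicate 10 or bcCML replicate 1. The list's call was lost under limma voom and under the replicate block. Of 9 dendritic cell genes 5 fell and 1 rose, both ways of adjusting (camera adjusted p = 0.00812; adjusted p = 0.0928 with an estimated correlation), with FCER1A, the IgE receptor alpha chain, falling by 3.20 ± 0.70. None rose without AML replicates 5, 6, 9 or 11 or BM replicates 1, 4, 5, 6 or 7.

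The B precursor and mature B cell scores lay below those of every BM library in all AML libraries but replicate 11. Of 18 B precursor genes 4 fell (MME, AKAP12, RAG1 and RAG2) and 0 rose, both ways of adjusting (camera adjusted p = 3.78e-08; adjusted p = 0.0984 with an estimated correlation). The B precursor score was 1.80 ± 1.87 in AML (SD, n = 11) and 5.63 ± 1.09 in BM (SD, n = 7), below the BM median in 10 of 11 AML libraries (exact permutation, adjusted p = 0.00204). In the mature B cell list only MS4A1 fell, by 3.36 ± 1.10 (SE), and 0 genes passed when adjusted over the list alone. Its camera test was negative (adjusted p = 0.000748; adjusted p = 0.234 with an estimated correlation), while the median of its fold changes was 0.60 and the mean 0.49. The MS4A1 call was lost with DESeq2, without a filter, and without BM replicates 1 (-3.15), 4 (-3.26), 5 (-3.22) or 6 (-3.20). Of 12 plasma cell genes 5 fell and 0 rose, both ways of adjusting (camera adjusted p = 1.35e-05; adjusted p = 0.0175 with an estimated correlation). IGHG1, an immunoglobulin heavy chain gene, fell by 6.69 ± 0.99. Without AML replicate 11 the changes were -5.47 for RAG1, -3.58 for RAG2, -10.26 for AKAP12, -5.26 for MS4A1 and -7.63 for IGHG1, and without AML replicate 9 that of MME was -6.89. RAG1 lost its call without BM replicates 1, 4, 5 or 6 (-2.63 to -2.49). The lower members numbered 12 for B precursor and 8 for mature B cell genes without AML replicate 11, and without AML replicate 8 the latter had 2.

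Among 16 leukaemia-associated antigens 8 rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 0.00215; adjusted p = 0.103 with an estimated correlation). Besides WT1 these included IL1RAP, a co-receptor of interleukin 1, at a log2 fold change of 3.14 ± 0.57 (SE), and CD96, a surface receptor of T and NK cells, at 3.39 ± 1.06. The antigen score was 4.66 ± 0.49 in AML and 3.44 ± 0.24 in BM (SD, n = 11 and 7; exact permutation, adjusted p = 0.000297). Of 23 p53 targets 9 rose and 0 fell, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00275; adjusted p = 0.16 with an estimated correlation). BAX, a pro-apoptotic BCL2 family member, rose by 0.83 ± 0.13, and CDKN1A, the cell-cycle inhibitor p21, by 3.39 ± 0.87, and by 2.72 without AML replicate 11. The p53 target score was above the BM median in 9 of 11 AML libraries (difference 0.52, exact permutation, adjusted p = 0.00521). With the median of the members in place of their mean the difference was 0.30 and did not pass (exact permutation, adjusted p = 0.134).

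Of 24 stem and progenitor genes 6 fell, among them MLLT3, and ANGPT1, which encodes angiopoietin 1, rose; the counts were the same adjusted over the list alone. MYCT1, a gene of the stem cell list, fell by 7.77 ± 1.27 (SE), and was -8.55 without AML replicate 11, while CD34 (0.70 ± 0.39) and KIT (-0.94 ± 0.61), a receptor of progenitors, did not pass. The list was called lower (camera adjusted p = 0.0117; adjusted p = 0.316 with an estimated correlation), but this call was lost under limma voom and under the replicate block, and the median of its members was -0.03. The score was below the BM median in 11 of 11 AML libraries (difference -1.69, exact permutation, adjusted p = 0.000163) and did not pass with the median of the members (difference -0.61, exact permutation, adjusted p = 0.265). Of 23 proliferation genes 4 fell, and 16 adjusted over the list alone (camera adjusted p = 1.7e-09; adjusted p = 0.278 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell by 1.67 ± 0.47. The lower proliferation genes were 22 in place of 4 without AML replicate 11, and without bcCML replicates 1 and 9 they were 8 and 7. They were 2 without AML replicates 1, 2, 4, 5, 6, 8 or 9 or BM replicates 2, 5 or 7, and 1 without BM replicates 1, 4 or 6. Of the stem and progenitor genes 2 rose without AML replicate 3. The marrow stroma and endothelium list was lower, with 3 of 7 members down both ways of adjusting (camera adjusted p = 0.0068; adjusted p = 0.0743 with an estimated correlation), though not under limma voom. CXCL12, a chemokine of marrow stroma, had 3 counts in AML and 378 in BM, a BM to AML ratio of 210 (95% counting interval 71.4 to 1020). The ratio was 114 without BM replicate 1 (38.5 to 559) and 564 without AML replicate 1 (101 to 22400).

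The other lists were not called in AML versus BM. In the HOXA and HOXB cluster 2 of 17 passed, both higher, and 0 adjusted over the list alone. HOXB6 rose by 3.98 ± 1.44 (SE), a call lost without AML replicates 1, 2, 4, 5, 6, 7 or 9, bcCML replicates 3 or 7 or any BM library (3.61 to 4.09). PBX3, a HOX cofactor, rose by 1.47 ± 0.51, a call lost without a filter, under the replicate block, and when AML replicate 1, 5, 6, 7 or 9 or any BM library was left out (1.32 to 1.50). The cluster had 5 higher without AML replicate 3 and 4 without AML replicate 11. HOXA9 (1.26 ± 0.82) and its partner MEIS1 (1.51 ± 0.73) did not pass. In the 17-gene stemness score 3 rose, DPYSL3 and ZBTB46 among them, and the list had an adjusted p of 0.812. Of the interferon genes 5 of 22 rose, including IRF9, a signal transducer of interferon, by 1.69 ± 0.38 (list adjusted p = 0.614). IRF9 was low in both groups, at 0.80 to 2.51 CPM in AML and 0.12 to 0.96 CPM in BM. The 5 became 3 without AML replicate 5 or BM replicates 1 or 4, 2 without BM replicates 5 or 7 and 1 without BM replicate 6, and 2 fell without AML replicate 11. Of the immediate early and stress genes 5 of 24 rose, including IER2 by 1.66 ± 0.47, and 2 fell (list adjusted p = 0.548). The higher were 3 without AML replicates 1 or 7 or BM replicate 3, and 2 without AML replicates 5, 9 or 10 or any other BM library. The lower were 1 without AML replicates 1 to 5 or 8 to 10 or BM replicates 4, 5 or 7, and 0 without BM replicate 6. The JAK-STAT and RAS-MAPK feedback list had 4 members higher and 1 lower of 21, with SOCS1, a cytokine-signalling inhibitor, up by 3.74 ± 0.77 (list adjusted p = 0.635; median and test negative, mean 0.27). Its lower member lost the call without any BM library, AML replicates 1, 2 or 4 to 9 or bcCML replicates 3 to 7 or 10. The lower were 2 without AML replicates 10 or 11 or bcCML replicates 8 or 9, and 3 without bcCML replicate 2. In the T cell list CD3D rose, by 5.18 without AML replicate 8, and CD40LG fell, with 3 counts in AML and 228 in BM, a BM to AML ratio of 127 (95% counting interval 42.9 to 620). That list had an adjusted p of 0.143, with a negative test beside a positive median and mean, and a score below the BM median in 9 of 11 AML libraries (difference -1.26, exact permutation, adjusted p = 0.0206). It had 3 lower without AML replicate 11. Of 6 natural killer and cytotoxic genes PRF1 and the chemokine CCL5 rose, CCL5 by 4.74 ± 0.81 (list adjusted p = 0.166). That list's score was above the BM median in 11 of 11 AML libraries (difference 1.15, exact permutation, adjusted p = 0.00264). The oncogene cooperation list had FAS higher, by 1.08 ± 0.25, as its only change among 17 (list adjusted p = 0.287). There were 2 higher without AML replicates 2, 4 or 7 or bcCML replicates 1, 2, 8 or 9, and 3 without AML replicate 11. Its score was below the BM median in 11 of 11 AML libraries (difference -0.76, exact permutation, adjusted p = 0.000163), and not past the threshold with the median of the members (difference -0.05, exact permutation, adjusted p = 0.917). MHC class II (adjusted p = 0.614) and mitochondrially encoded genes (adjusted p = 0.252) had 0 members past the threshold.

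By the camera test at the preset correlation 15 of the 26 lists were called in AML versus BM, and 3 held with an estimated correlation: erythroid, secondary and tertiary granule, and plasma cell. Some random splits of the same libraries called as many lists, so these calls alone do not exclude chance; the exact tests of scores per library do not share this weakness. With a test against a log2 fold change of 1 the 3430 genes became 430, and with limma voom 8557. The other strongly changed genes of the naming rule were GGT5 (log2 fold change 5.57 ± 0.98 SE), a gamma-glutamyl transferase, MAMDC2 (4.82 ± 1.30) and VNN1 (4.28 ± 1.30), a pantetheinase, all higher, and DSG2 (-9.01 ± 1.08), a desmosomal cadherin, and AKAP12 (-9.42 ± 1.17), a kinase-anchoring scaffold, both lower. WT1 lies on chromosome 11 (32387775 to 32435630, GRCh38), GGT5 on chromosome 22 (24219654 to 24245142) and CA1 on chromosome 8 (85327608 to 85379014), all protein-coding genes.

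**Figure D2:**
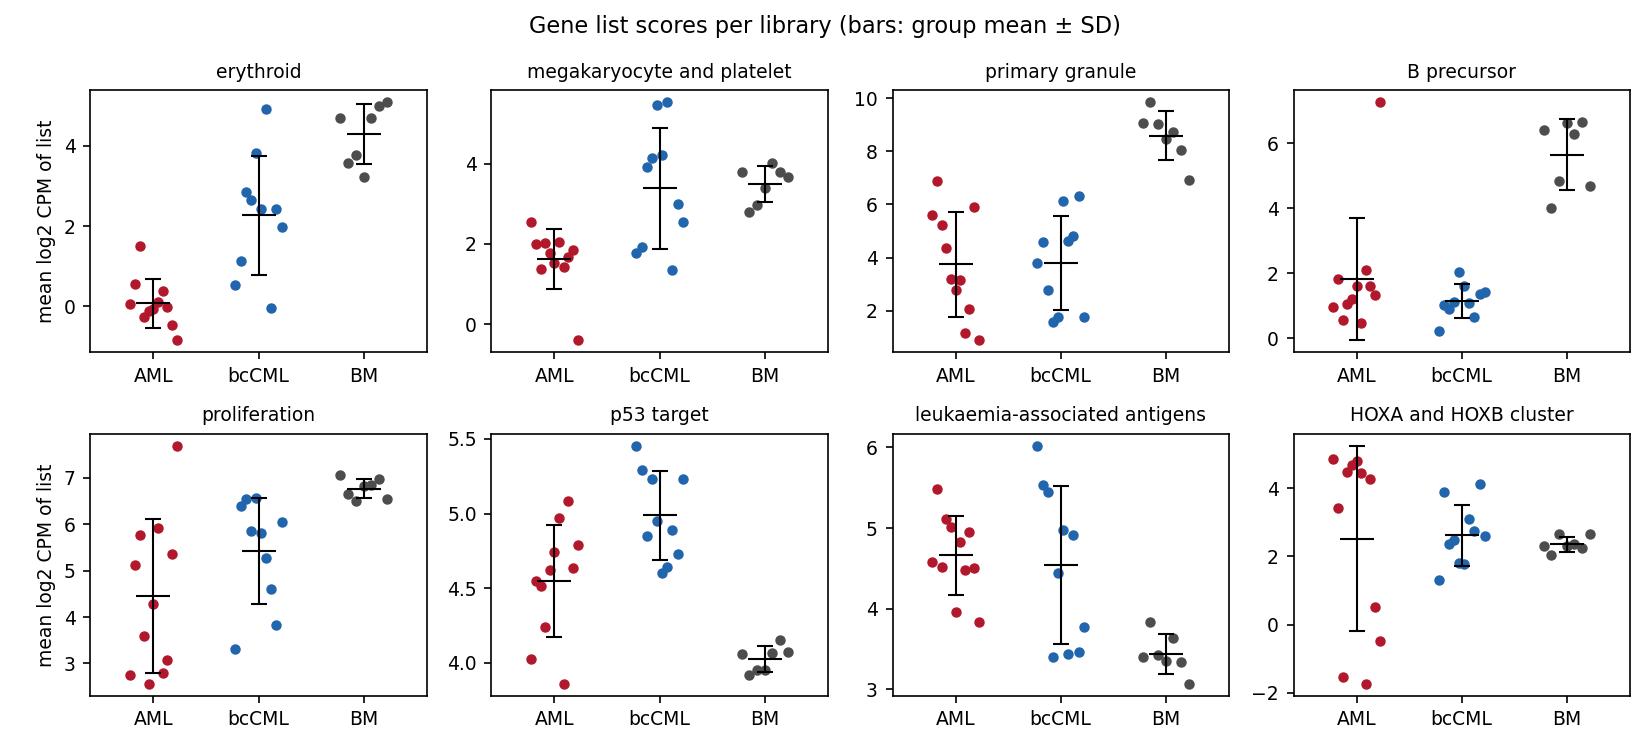
Scores of 8 gene lists per library, as the mean log2 CPM of the list's tested members, for AML (n = 11), bcCML (n = 10) and BM (n = 7); points are libraries and bars the group mean ± SD. The erythroid mean is 0.08 in AML, 2.27 in bcCML and 4.29 in BM, and 1 AML library lies above every BM library for B precursor genes.

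In bcCML, B-lineage and primary granule genes were lower than in BM, and p53 targets, cytokine-feedback genes and leukaemia antigens were higher. The B precursor, plasma cell, primary granule and p53 target lists held with an estimated correlation, and mature B cell (adjusted p = 0.0752 with an estimated correlation), feedback (0.336) and antigen genes (0.106) did not. The feedback call was also lost under limma voom and without bcCML replicate 2. MME, the CD10 peptidase of early lymphoid cells, had a median of 0.357 CPM in bcCML and 120 CPM in BM (log2 fold change -6.68 ± 1.09 SE, n = 10 and 7, edgeR adjusted p = 0.000794). VPREB3, of the pre-B cell receptor, fell by 8.76 ± 1.72 and DNTT, the template-free DNA polymerase of lymphoid precursors, fell by 7.21 ± 1.56, each in 10 of 10 libraries. DNTT was -8.29 without bcCML replicate 2. WT1 rose 16.6-fold (log2 fold change 4.06 ± 0.47, adjusted p = 3.56e-05), and BBC3, the pro-apoptotic p53 target PUMA, rose 8.71-fold (3.12 ± 0.45, adjusted p = 0.000495). In all, 1211 genes changed, 859 higher and 352 lower in bcCML.

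Of 18 B precursor genes 10 fell and 0 rose, and 14 fell when adjusted over the list alone (camera adjusted p = 6.22e-16; adjusted p = 0.0241 with an estimated correlation). The B precursor score was 1.14 ± 0.51 in bcCML (SD, n = 10) and 5.63 ± 1.09 in BM (SD, n = 7), below the BM median in 10 of 10 libraries (exact permutation, adjusted p = 0.000446, the smallest these permutations give). Of 12 mature B cell genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 6.37e-07; adjusted p = 0.0752 with an estimated correlation), with MS4A1 down by 7.24 ± 1.41 (SE). POU2AF1, a B cell transcriptional coactivator, fell by 7.53 ± 1.80. Of 12 plasma cell genes 4 fell and 0 rose, with 5 lower and 1 higher adjusted over the list alone, IGHG1 by 6.61 ± 1.03 and by 7.93 without bcCML replicate 2 (camera adjusted p = 3.31e-05; adjusted p = 0.0131 with an estimated correlation). In the mature B cell list 6 fell without AML replicate 11. Under limma voom the calls of MME, VPREB3, POU2AF1 and IGHG1 were lost.

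Of 13 primary granule genes 8 fell and 0 rose, 10 adjusted over the list alone, SERPINB10 by 5.81 ± 1.03 (SE) (camera adjusted p = 7.91e-12; adjusted p = 0.0329 with an estimated correlation). The primary granule score was 3.82 ± 1.77 in bcCML and 8.58 ± 0.91 in BM (SD, n = 10 and 7; exact permutation, adjusted p = 0.000446). MPO had a median of 36.1 CPM in bcCML and 11300 CPM in BM and did not pass (log2 fold change -4.21 ± 1.48, adjusted p = 0.078); without bcCML replicate 9 it passed at -5.73, and it passed with DESeq2 and limma voom. In the secondary and tertiary granule list 3 of 10 fell, with CEACAM6, a granulocyte adhesion protein, down by 6.85 ± 0.96, and CHI3L1, a chitinase-like protein, rose (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 7.89e-05; adjusted p = 0.0329 with an estimated correlation). That list's call was lost under limma voom, and 5 fell without BM replicate 6. The eosinophil, basophil and mast cell list was called lower (camera adjusted p = 0.0117; adjusted p = 0.341 with an estimated correlation) although the median of its fold changes was 0.42 and the mean -0.10, and not under limma voom. EPX, eosinophil peroxidase, fell by 5.98 ± 0.90 with 4 others, and IL1RL1, the interleukin 33 receptor of mast cells, rose; adjusted over the list alone 5 fell and 3 rose. Of that list 2 rose without bcCML replicate 7 or BM replicate 1. Of 9 dendritic cell genes 2 fell, IRF8, a transcription factor of dendritic and monocyte precursors, by 5.46 ± 0.94, and LILRA4, a receptor of plasmacytoid cells (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00169; adjusted p = 0.0329 with an estimated correlation). TIFAB, an inhibitor of the adaptor TIFA, fell by 6.45 ± 1.04. Without bcCML replicate 2 the changes were -8.01 for TIFAB, -6.62 for EPX, 4.98 for CHI3L1 and 4.76 for IL1RL1, without replicate 3 -7.64 for CEACAM6, and without replicate 9 -6.87 for SERPINB10.

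Of 21 erythroid genes 3 fell and 0 rose, AHSP by 4.60 ± 0.80 (SE) and by 5.38 without bcCML replicate 7, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.02e-07; adjusted p = 0.147 with an estimated correlation). The 3 became 1 without BM replicates 5, 6 or 7 and 5 without bcCML replicate 7. The erythroid score was 2.27 ± 1.48 in bcCML against 4.29 ± 0.75 in BM (SD, n = 10 and 7; exact permutation, adjusted p = 0.0102). HBB had a log2 fold change of -2.88 ± 0.94 (adjusted p = 0.0575) and passed without bcCML replicate 7, at -3.80, and with DESeq2 and limma voom. Megakaryocyte and platelet genes did not differ by test, with 0 of 16 past the threshold (list adjusted p = 0.826); PF4 had a log2 fold change of 1.87 ± 1.06 and PPBP, another platelet chemokine, of 2.77 ± 1.15. Of the proliferation genes 0 of 23 passed, also adjusted over the list alone, while the list was called lower (camera adjusted p = 3.22e-06; adjusted p = 0.387 with an estimated correlation) and its score was below the BM median in 10 of 10 libraries (difference -1.35, exact permutation, adjusted p = 0.00167).

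Of 23 p53 targets 12 rose and 0 fell, 15 adjusted over the list alone (camera adjusted p = 8.53e-10; adjusted p = 0.0131 with an estimated correlation). Besides BBC3 these included CDKN1A (log2 fold change 3.51 ± 0.88 SE, 2.87 without bcCML replicate 2), TNFRSF10B, a TRAIL death receptor (1.60 ± 0.33), and ZMAT3, an RNA-binding p53 target (1.80 ± 0.46). The p53 target score was 4.99 ± 0.30 in bcCML and 4.03 ± 0.08 in BM (SD, n = 10 and 7), above the BM median in 10 of 10 libraries (exact permutation, adjusted p = 0.000446). FAS, a death receptor that is also in the oncogene cooperation list, rose by 1.47 ± 0.26. Of 21 JAK-STAT and RAS-MAPK feedback genes 6 rose, SOCS1 by 5.01 ± 0.81 and PIM2, a survival kinase induced by cytokines, by 2.28 ± 0.39, and 7 adjusted over the list alone (camera adjusted p = 0.0293; adjusted p = 0.336 with an estimated correlation). This list's call was lost under limma voom and without bcCML replicate 2. Of 16 leukaemia-associated antigens 6 rose, also adjusted over the list alone, including IL2RA, the interleukin 2 receptor alpha chain, by 4.85 ± 1.21 (camera adjusted p = 0.00171; adjusted p = 0.106 with an estimated correlation); its score passed with the mean of the members (difference 1.10, exact permutation, adjusted p = 0.0201) and not with their median (difference 0.86, exact permutation, adjusted p = 0.2). Of 6 natural killer and cytotoxic genes PRF1, perforin, rose by 5.25 ± 1.14 and CCL5 by 3.71 ± 0.77, and 4 passed adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.142 with an estimated correlation), a call lost under limma voom.

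The stem and progenitor list was called lower (camera adjusted p = 0.015; adjusted p = 0.341 with an estimated correlation) with 1 of 24 members past the threshold and 0 adjusted over the list alone. That member, GATA2, a stem cell transcription factor, was higher, by 1.64 ± 0.50 (SE). Its call was lost with library totals alone, without a filter, under the replicate block, and when AML replicate 9, bcCML replicate 2, 9 or 10 or any BM library was left out (1.10 to 1.74). The list's call was lost without bcCML replicate 2 as well. MHC class II genes had 0 of 12 past the threshold, and the list's lower call (camera adjusted p = 0.0323; adjusted p = 0.638 with an estimated correlation) was lost under the replicate block and without bcCML replicates 2, 4, 8 or 10, with medians of -0.10, -0.07, -0.09 and -0.07. Not called were the 17-gene stemness score (DNMT3B, a de novo DNA methyltransferase, at 1.80 ± 0.57; list adjusted p = 0.292), the HOXA and HOXB cluster (0 of 17, adjusted p = 0.346), mature neutrophil (CREB5 higher; adjusted p = 0.0734), and monocyte and macrophage genes (1 higher, CLEC7A, the beta-glucan receptor dectin-1, by 3.96 ± 1.01 and by 2.99 without bcCML replicate 5, and 2 lower; adjusted p = 0.097). Nor were T cell genes (2 higher, among them CD3D; adjusted p = 0.826, a negative test beside a median of 1.84), marrow stroma (CXCL12 lower, by 3.96 without BM replicate 1, and 1 higher; adjusted p = 0.234, a negative test beside a median of 0.19), interferon response (RSAD2 higher; adjusted p = 0.346), immediate early and stress (5 of 24 higher, adjusted p = 0.474), oncogene cooperation (3 past the threshold, FAS higher among them; adjusted p = 0.772) and mitochondrially encoded genes (0 of 13, adjusted p = 0.474). The mature neutrophil score was below the BM median in 10 of 10 libraries (difference -0.97, exact permutation, adjusted p = 0.00153). Counts in these lists moved with single libraries. The lower monocyte and macrophage genes were 1 without bcCML replicate 3 or BM replicates 1, 2, 4 or 5, and the higher T cell genes 1 without bcCML replicates 1 to 5, 8 or 10. The immediate early genes were 2 without BM replicates 1 to 5 or 7 and 3 without bcCML replicate 9. The higher marrow stroma gene was lost without AML replicate 9, bcCML replicates 3, 5 or 7 or any BM library, and CXCL12 fell below the count filter without bcCML replicate 7. Of the oncogene cooperation genes the 2 higher became 1 without bcCML replicate 1 or any BM library, and the lower was lost without bcCML replicates 3, 5 or 8 or BM replicates 1 to 5. Several of these single calls were weak. Those of DNMT3B, RSAD2 and CREB5 were lost under the replicate block. That of DNMT3B was also lost when any 1 of 22 libraries was left out (1.46 to 1.84; all but AML replicates 10 and 11 and bcCML replicates 1, 2, 7 and 9). That of RSAD2 was lost without bcCML replicate 1 or 10 or BM replicates 1 to 6 (as low as 1.71, without replicate 10 of bcCML), and that of CREB5 without bcCML replicate 9 (2.33) or BM replicate 1, 2, 3 or 7 (3.58 to 3.70). CXCL8, a neutrophil chemokine, had a log2 fold change of 6.36 ± 1.63, 4.96 without bcCML replicate 2 and 2.32 under limma voom, where it did not pass. IER3, a stress-response gene, had 6.46 ± 1.65, and 2.20 without bcCML replicate 2, where it did not pass. PIEZO2, a mechanosensitive channel (4.66 ± 1.28), and TMEM273 (4.62 ± 1.28) lost their calls without a filter. The first also lost it without BM replicate 2, 4, 5 or 6 (4.53 to 4.64), the second without BM replicate 1, 2, 3, 4 or 6 (4.52 to 4.63).

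Of the 26 lists 15 were called in bcCML versus BM, and 6 held with an estimated correlation: primary granule, secondary and tertiary granule, dendritic cell, B precursor, plasma cell and p53 target. The 1211 genes became 793, 702, 736, 714 and 779 without BM replicates 1, 2, 4, 5 and 6, and 101, 2289 and 3220 with a test against a log2 fold change of 1, DESeq2 and limma voom. MME lies on chromosome 3 (155024124 to 155183729, GRCh38) and BBC3 on chromosome 19 (47220822 to 47232766), both protein-coding.

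**Figure D3:**
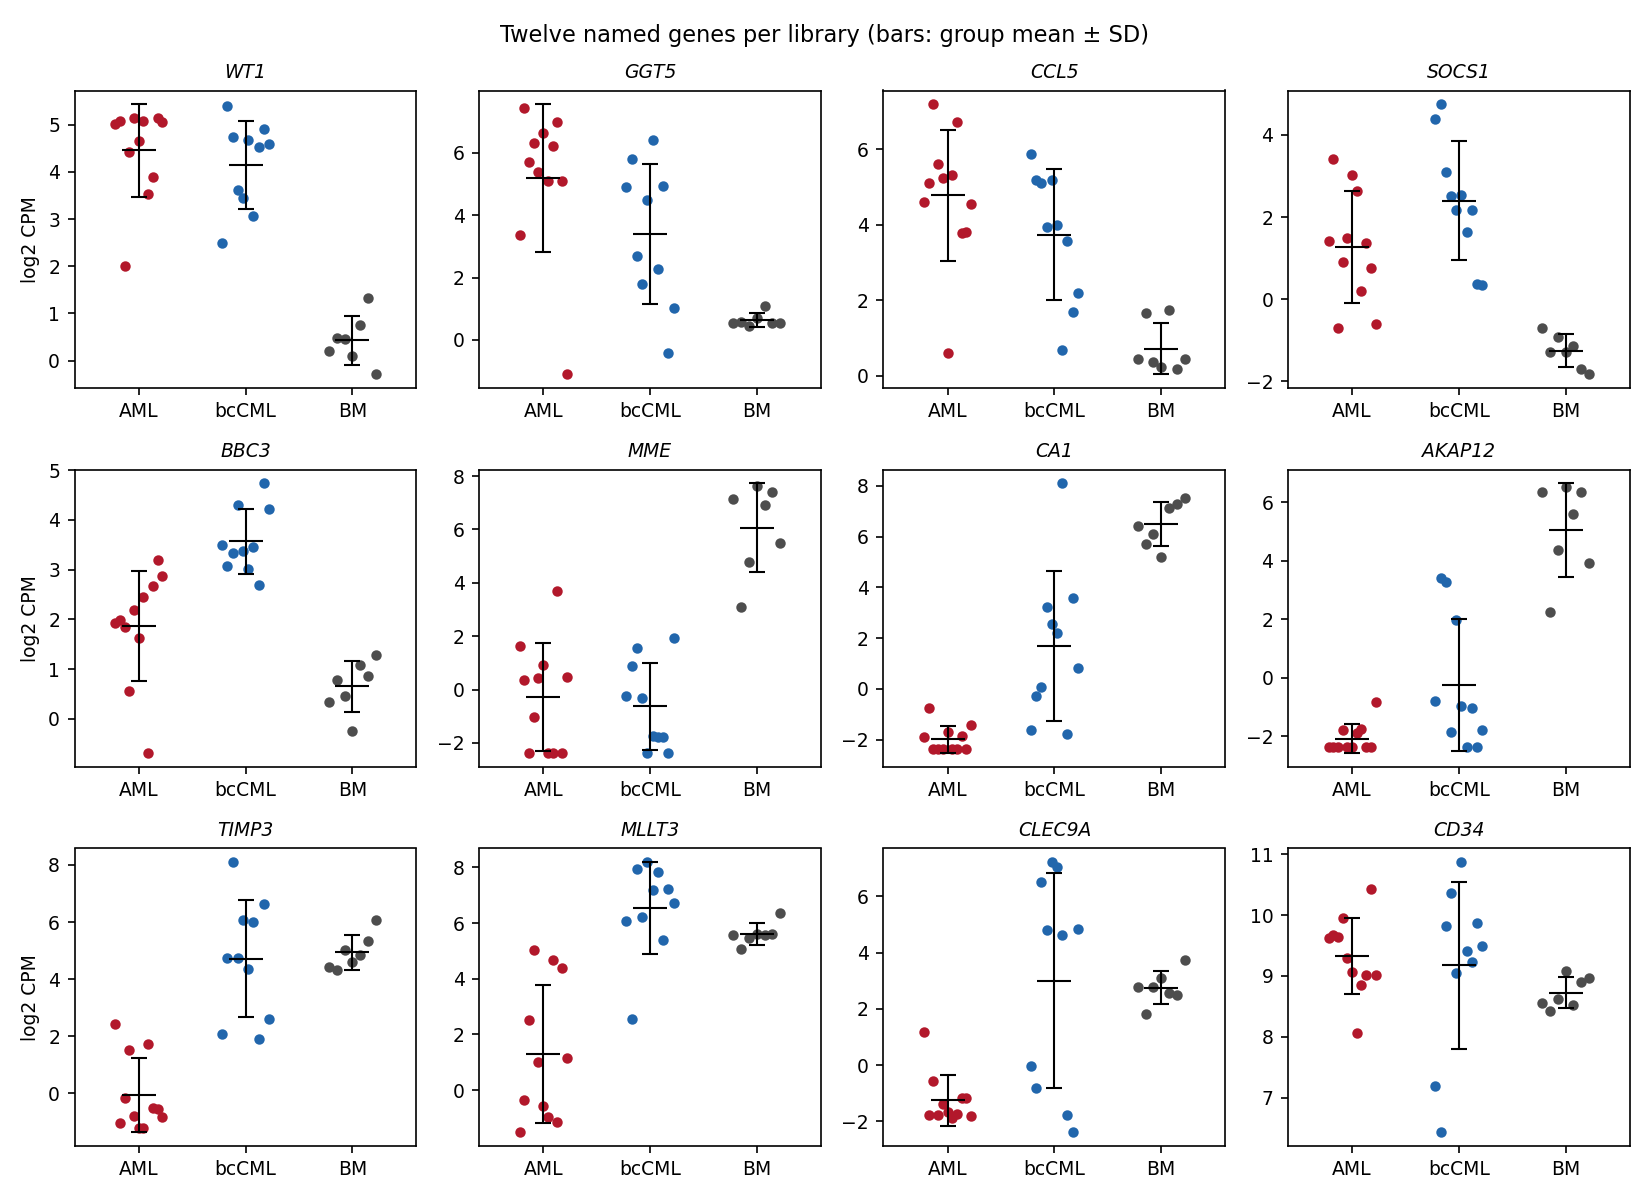
Log2 CPM of 12 named genes per library in AML (n = 11), bcCML (n = 10) and BM (n = 7); points are libraries and bars the group mean ± SD. WT1 means are 4.46 in AML, 4.15 in bcCML and 0.43 in BM, and CA1 means are -1.99 in AML and 6.48 in BM.

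Between the leukaemias, bcCML had more transcript of erythroid, megakaryocyte, mast cell and late granule genes than AML, and less of the single genes TYROBP, PLD4 and RAB7B. None of these 4 lists held (adjusted p = 0.178, 0.178, 0.178 and 0.242 with an estimated correlation), and the late granule call was lost without bcCML replicate 2. The 3 single genes do not stand for myeloid genes as a whole. Of 15 monocyte and macrophage genes 2 were higher and 0 lower, and of 13 primary granule genes 1 was higher and 0 lower. Of 12 mature neutrophil genes 0 were higher and 2 lower. TYROBP was not called in a fit of these groups alone. TIMP3, an inhibitor of matrix metalloproteinases, was 45.2-fold higher in bcCML (log2 fold change 5.50 ± 0.77 SE, n = 10 and 11, edgeR adjusted p = 0.000126), above the AML median in 10 of 10 libraries. HBB was 36.9-fold higher (5.20 ± 0.98, adjusted p = 0.00154), with medians of 30.5 CPM in bcCML and 0.12 CPM in AML. The change of HBB was 4.29 without bcCML replicate 7 and 6.09 without AML replicate 3, and that of TIMP3 4.74 without bcCML replicate 3. MLLT3, a chromatin reader that maintains stem cells, was 16.7-fold higher (4.07 ± 0.79), and TYROBP, a signalling adaptor of myeloid cells, was 4.94-fold lower (-2.30 ± 0.58). In all, 1602 genes differed in the fit over all 3 groups, 945 higher and 657 lower in bcCML. A fit of these groups alone called far fewer.

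Of 21 erythroid genes 14 were higher and 0 lower in bcCML, 17 adjusted over the list alone, with RHAG, a red-cell membrane channel, up by 7.40 ± 1.11 (SE) (camera adjusted p = 1.66e-11; adjusted p = 0.178 with an estimated correlation). The erythroid score was 2.27 ± 1.48 in bcCML and 0.08 ± 0.61 in AML (SD, n = 10 and 11; permutation test, adjusted p = 0.00624). Of 16 megakaryocyte and platelet genes 9 were higher, 12 adjusted over the list alone (camera adjusted p = 4.5e-06; adjusted p = 0.178 with an estimated correlation), with PF4 up by 6.0 ± 1.12 and ITGB3, platelet integrin beta 3, by 5.65 ± 1.04. The megakaryocyte score was 3.38 ± 1.50 in bcCML and 1.62 ± 0.75 in AML (SD; permutation test, adjusted p = 0.0109). Of 16 eosinophil, basophil and mast cell genes 6 were higher, 10 adjusted over the list alone, with IL1RL1 up by 5.99 ± 0.99 (camera adjusted p = 4.5e-06; adjusted p = 0.178 with an estimated correlation); the score was above the AML median in 10 of 10 libraries (difference 1.85, permutation test, adjusted p = 0.00676). Without bcCML replicate 5 the changes were 5.96 for RHAG and 5.29 for PF4, 4.4 for IL1RL1 without bcCML replicate 2, and 6.30 for ITGB3 without AML replicate 2.

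Of 10 secondary and tertiary granule genes 5 were higher, 7 adjusted over the list alone (camera adjusted p = 0.0164; adjusted p = 0.242 with an estimated correlation), but not without bcCML replicate 2, under limma voom or in a fit of these groups alone. CRISP3, of specific granules, had 3 counts in AML and 758 in bcCML, a ratio of 286 (95% counting interval 97.6 to 1390), and 178 without bcCML replicate 6 (60.5 to 866). The AML counts were all in replicate 9. Of 7 marrow stroma and endothelium genes 3 were higher, both ways of adjusting (camera adjusted p = 0.0164; adjusted p = 0.178 with an estimated correlation), TEK, the angiopoietin receptor, by 7.32 ± 1.31 (SE) and by 5.54 without bcCML replicate 3. This list's call was lost under limma voom and in a fit of these groups alone. The JAK-STAT and RAS-MAPK feedback list had 4 of 21 higher, also adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.178 with an estimated correlation), with BCL2L1, an anti-apoptotic STAT5 target, up by 1.29 ± 0.27; its score was above the AML median in 10 of 10 libraries (difference 0.94, permutation test, adjusted p = 0.00676), though not past the threshold with the median of the members. Without bcCML replicate 2 the 4 became 2, with DUSP4, a MAPK phosphatase, going from 4.50 to 1.09 and CCND1, cyclin D1, from 3.65 to 2.78, and neither passed. CCND1 also lost its call without bcCML replicate 3 (3.03). That list's call was lost under limma voom. Of 23 p53 targets 3 were higher, 4 adjusted over the list alone, CCNG1, cyclin G1, by 1.16 ± 0.21 (camera adjusted p = 0.0147; adjusted p = 0.333 with an estimated correlation), a call lost under limma voom and without bcCML replicate 1. The p53 score passed with the mean of the members (difference 0.44, permutation test, adjusted p = 0.024) and not with their median (difference 0.26, permutation test, adjusted p = 0.247). The proliferation list was called higher (camera adjusted p = 0.000219; adjusted p = 0.642 with an estimated correlation) with 0 of 23 members past the threshold, and its score did not pass (permutation test, adjusted p = 0.312). It had 5 higher without AML replicate 11.

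The remaining lists were not called. In the stem and progenitor list 4 genes were higher, MLLT3 among them, and 1 lower (list adjusted p = 0.452). The lower call was lost without AML replicates 1, 2, 4, 6, 7 or 9, bcCML replicates 3 to 6 or 10 or BM replicates 1 or 5, and 2 were lower without bcCML replicate 9. Of 9 dendritic cell genes CLEC9A, a receptor of cross-presenting cells, was higher by 6.91 ± 1.07 (SE), and by 7.86 without AML replicate 1, with FCER1A, and IRF7, an interferon regulator, was lower by 1.16 ± 0.26 with 1 other gene (list adjusted p = 0.915; median and mean negative, test positive). Only 1 was lower without AML replicate 11. Of the monocyte and macrophage genes S100A12 and CD14 were higher, CD14 by 4.26 ± 1.05 (list adjusted p = 0.057). CD14 was 3.29 without bcCML replicate 2 and 5.02 and 4.92 without AML replicates 2 and 10. Of the T cell genes 4 of 15 were higher (list adjusted p = 0.0559), among them CD40LG, with 301 counts in bcCML and 3 in AML, a ratio of 114 (95% counting interval 38.5 to 555). Most of these counts were in bcCML replicates 7 and 9 (11.6 and 23.0 CPM), and without replicate 9 the ratio was 54.4 (18.2 to 267). Without bcCML replicates 4 or 10 the 4 became 2. The B precursor list had 9 of 18 lower and 1 higher (list adjusted p = 0.141), and the mature B cell list 6 of 12 lower (list adjusted p = 0.433). Most of these B-lineage differences followed AML replicate 11. Without it 1 B precursor and 0 mature B cell genes were lower and 2 B precursor genes higher. CD79B went from -2.26 ± 0.64 to -0.86 and FCRLA from -6.92 ± 1.70 to -2.55, and neither then passed, while DNTT went from -5.26 to -4.51 and still did. DNTT was -6.35 without bcCML replicate 2. The lower mature B cell genes were 3 without bcCML replicates 3 or 6 to 10 or BM replicates 1 or 3 to 7. Of the oncogene cooperation genes 0 of 17 passed (2 without bcCML replicate 8; list adjusted p = 0.0578), with ID2, an inhibitor of DNA binding, at 1.69 ± 0.56; the score was higher in bcCML (difference 0.68, permutation test, adjusted p = 0.0202) but not with the median of the members (difference 0.40, permutation test, adjusted p = 0.247).

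Not called either were plasma cell (XBP1, a secretory-cell transcription factor, higher by 0.99 ± 0.20 SE; list adjusted p = 0.251), mature neutrophil (2 lower, CMTM2 among them; adjusted p = 0.449), interferon response (3 past the threshold, IRF7 lower among them; adjusted p = 0.078), MHC class II (adjusted p = 0.109), mitochondrially encoded genes (adjusted p = 0.449), natural killer and cytotoxic genes (adjusted p = 0.501) and the 17-gene stemness score (adjusted p = 0.449). In the last 4 lists 0 members passed. Plasma cell genes higher were 2 without AML replicates 9 or 11 or bcCML replicates 1 or 8. The lower mature neutrophil genes were 1 without any of 23 libraries (all but AML replicates 3, 8 and 11 and bcCML replicates 1 and 8). The lower interferon genes were 1 without AML replicate 1. The primary granule list had only MS4A3 higher, by 2.66 ± 0.81, a call lost under limma voom, without a filter, in a fit of these groups alone, and when any of AML replicates 1 to 9 or bcCML replicate 2 or 8 was left out (2.21 to 2.68; 4.18 without AML replicate 10; list adjusted p = 0.65). The antigen list had only CD70, a TNF family ligand, higher, by 3.05 ± 0.97, a call lost without a filter and when any of AML replicates 1 to 10, bcCML replicate 3 or any BM library was left out (2.91 to 3.05; list adjusted p = 0.499). CD70 fell below the count filter without AML replicate 11 or bcCML replicates 2, 4 or 10. The immediate early list had only IER3 higher, by 4.18 ± 1.18, which was -0.08 without bcCML replicate 2 (list adjusted p = 0.915). That list had 2 higher without AML replicates 6 or 9 or bcCML replicates 1, 4 or 6, and 3 without AML replicate 7 or bcCML replicates 5, 7 or 8. For the HOXA and HOXB cluster (0 members past the threshold, adjusted p = 0.915) and the primary granule list the median was negative and the test positive, for the immediate early list the median was positive and the test negative, and for the antigen list the median and test were negative and the mean 0.08.

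The genes lower in bcCML under the naming rule were RAB7B, a GTPase of late endosomes (-3.01 ± 0.72 SE), PLD4, a nuclease of dendritic cells and monocytes (-2.91 ± 0.62), UMODL1 (-2.89 ± 0.59), TYROBP and CD79B. LTBP1, a TGF-beta binding protein (4.63 ± 0.91, and 3.83 without bcCML replicate 2), and SCD, stearoyl-CoA desaturase (3.86 ± 0.71), were higher, each above the AML median in at least 9 of 10 libraries. CD3E was called higher (3.74 ± 1.10) on the strength of bcCML replicates 4 and 10, at 173 and 73.9 CPM, and lost its call without either, at 2.23 and 3.39, without AML replicates 2, 5 or 9 (3.64 to 3.66), and was 4.72 without AML replicate 8. The call was lost too under limma voom. In a fit of only these groups the 1602 genes became 339, and TYROBP, CD79B and MS4A3 were not among them. The fit over all libraries took part of its estimate of the spread from BM, which is not in this contrast. Genes varied less there, with a median SD of log2 CPM of 0.24 against 0.51 in AML and 0.67 in bcCML. With limma voom, which gave 2185 genes, the calls of RHAG, HBB, PF4, ITGB3, CLEC9A, TEK, MYCT1, CRISP3, CD40LG and S100A12 were lost, with fold changes in the same direction. With library totals alone 41.3% of the called genes were higher in bcCML rather than 59%, since that scaling moved the median of all genes by -0.10. Of the 26 lists 8 were called and 0 held with an estimated correlation, and random splits of the libraries often called as many; by the permutation test of scores 8 lists passed. TIMP3 lies on chromosome 22 (32801701 to 32863043, GRCh38), and MLLT3 on chromosome 9 (20341665 to 20622543).

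Both leukaemias shared changes against BM. Among the genes changed in both comparisons 556 were higher in both, 220 lower in both and 5 opposite. WT1, IL1RAP, IL2RA, CCL5, SOCS1, CISH, CDKN1A and FAS were higher in both, and MME, RAG2, MS4A3, ELANE, AHSP, EPX, IRF8 and LYZ were lower in both. In 10 simulations of unchanged groups, with BM drawn anew, edgeR called at most 9 and 3 genes in the comparisons, so their overlap of 0 says nothing about shared controls. Independent lists of these lengths would share 111 higher and 30.1 lower genes. The correlation of fold changes across genes, which are not independent replicates, was 0.633. It was 0.186 in simulations with each group's own spread and 0.615 with a spread shared by the groups, so its size alone does not separate shared effects from shared controls. The covariance was 0.764 against 0.0317 and 0.158, and the share of genes with the same sign 74.6% against 60.3% and 70.3%. With BM split into 4 and 3 libraries, so that no library served both comparisons, the median overlap over 10 splits was 10 higher (4 to 23) and 29 lower (19 to 38) genes, beside 0.84 and 1.83 for independent lists. The correlation was then 0.603 and the covariance 0.753. The shared counts were 318, 326, 334 and 352 higher without BM replicates 2, 4, 5 and 6, and 137, 146, 135 and 334 lower without BM replicates 1, 2 and 5 and AML replicate 11.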

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

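The tests of the B-lineage pattern, of the erythroid pattern, of scaling for the p53 targets and of random splits were chosen only after the result was seen, as was the final form of the comparison of opposite effects. The bounds for the adjusted p53 scores were set before those p-values were computed, though the scores themselves had been seen. That a correction which hardly moves either difference decides nothing was a rule set after those p-values were seen.

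AML replicate 11 expressed most B precursor genes at levels the other AML libraries did not reach. PAX5, a B cell identity factor, stood at 777 CPM against at most 8.01 CPM in the other AML libraries and 113 CPM in BM, VPREB1, of the pre-B cell receptor, at 456 CPM, and CD33, a myeloid surface protein, at 1.02 CPM. A swap with a BM library would leave a BM library out of place, and 0 of the 7 lay closer to another group, though replicate 11 itself lay closest to BM (0.83 against 0.793 for AML). That measure favours BM, whose libraries were the most alike. BM-like cells mixed in could not exceed their source, yet 10 of the 18 B precursor genes lay above the highest BM library, and mature B cells would carry abundant MS4A1, while its CPM was 0.0156 of that of PAX5. What stays open is a wrong label or a sample whose own leukaemic cells express this programme, which no test here separates.

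The p53 target score was higher in both leukaemias than in BM, by 0.52 in AML and 0.96 in bcCML. Handling stress is left open: the immediate early score differed from BM by only 0.10 and 0.06, so removing its slope within groups (0.137) left the differences at 0.51 and 0.95 (larger exact permutation p = 0.000943) and tested little. The same correction for the proliferation score (slope 0.0664) widened the differences to 0.68 and 1.05 (larger exact permutation p = 0.000126), which argues only against the part of fewer cycling cells that moves with this score within groups. With library totals alone the smaller median of the list's fold changes was 0.691, which argues against scaling as the whole source. Handling stress, unstated differences between donors and a p53 response in the leukaemic cells all stay open.

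The erythroid score was lower in every AML library than in every BM library. RNA of mature red cells in BM alone would spare the genes of nucleated precursors, but 5 of 5 (KLF1, GATA1, TAL1, RHAG and ANK1) were lower past the threshold. With most single libraries left out the calls of GATA1 and TAL1 were lost, while KLF1, RHAG and ANK1 passed each time. An even dilution of all normal lineages would lower the megakaryocyte score as much only if the leukaemic cells expressed neither list. The erythroid minus megakaryocyte difference was -1.54 ± 0.82 in AML and 0.80 ± 0.50 in BM (SD, n = 11 and 7, exact permutation p = 0.000126). That condition was not tested, and 11 of the 16 megakaryocyte and platelet genes did not pass in AML, so even dilution stays open. A smaller erythroid share in the AML samples, or its sorting out at collection, may contribute, and the design does not separate them.

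In bcCML and BM a single library lay far from the rest of its group 18 times. AML libraries were not checked in this way, so the absence of AML here says nothing about them. The 242 checks covered named genes and list scores, and the haemoglobin share below came from further checks of library measures. A hit was a gap to the nearest library, as a share of the group's range, above Dixon's 95% value. Chance passes that value in about 1 of 20 groups. In bcCML replicate 2 the hits were IER3 (share 0.528, log2 CPM 8.89 against a median of 0.40), IGHG1 (0.66), TIFAB (0.595), MLLT3 as the lowest (0.504), the secondary and tertiary granule score (0.469) and the JAK-STAT and RAS-MAPK feedback score (0.477). In bcCML replicate 7 they were CXCL12 (0.644) and the haemoglobin share of counts (0.579, 0.0665% against a median of 0.00551%). In bcCML replicate 9 they were LTF (0.468) and TMEM273 as the lowest (0.628), and in bcCML replicate 1 MCM2 (0.482) and SCD (0.588), both lowest. In BM they were GGT5 in replicate 5 (0.626), MYCT1 (0.613), MLLT3 (0.591) and IRF7 as the lowest (0.731) in replicate 7, and S100P (0.606) and the mature neutrophil score (0.735) as the lowest in replicate 6.

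For 22 of 95 named genes the fold changes against BM had opposite signs in the leukaemias and differed between them by the edgeR test of bcCML against AML. Higher in bcCML by this log2 difference were CRISP3 (7.6), RHAG (7.4), TEK (7.32), CLEC9A (6.91), CD40LG (6.62), PF4 (6.0), ITGB3 (5.65), TIMP3 (5.5), LTBP1 (4.63), CD14 (4.26), MLLT3 (4.07), SCD (3.86), CD3E (3.74), PPBP (3.3), BCL2L1 (1.29), CCNG1 (1.16) and XBP1 (0.99). Lower in bcCML were FCRLA (-6.92), RAB7B (-3.01), UMODL1 (-2.89), CMTM2 (-2.84) and IRF7 (-1.16). In CLEC9A the fold changes were -4.22 in AML and 2.68 in bcCML, and in TIMP3 -4.68 and 0.82. Some named genes were chosen for their difference between the leukaemias, so the count of 22 is partly set by that choice. The signs were taken without a test against BM, and some rest on values near 0, such as 0.17 in bcCML for CD40LG and -0.11 in AML for BCL2L1. Over all genes tested only 5 were called in opposite directions against BM. The difference of FCRLA rests on AML replicate 11, and that of CD3E on bcCML replicates 4 and 10. With 1 bcCML library left out the difference was 5.33 for CD40LG (replicate 9), 5.96 for RHAG and 5.29 for PF4 (replicate 5), 5.54 for TEK and 4.74 for TIMP3 (replicate 3), 6.78 for CRISP3 (replicate 6), and 3.29 for CD14 and 3.83 for LTBP1 (replicate 2). That of PPBP did not pass without bcCML replicate 5 (2.02) or AML replicates 2 (3.21) or 5 (3.22).

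Random splits of the samples into groups of the same sizes, 100 per comparison with the real one included, tested whether chance alone gives as much. Chance was excluded for the genes changed in each comparison, where 1 of 100 splits, the real one, reached the count: 3430 against at most 2140 in other splits for AML versus BM, 1211 against 330 for bcCML versus BM and 1602 against 387 for bcCML versus AML. For the shared genes, 556 higher and 220 lower, 1 split reached each count and the highest other was 0, but most other splits called 0 genes in each comparison, so these zeros do not test the sharing itself. For the lists it was excluded only narrowly for bcCML versus BM, where 4 splits called 15 or more, the real one and 3 that equalled it (highest other 15). It was not excluded for AML versus BM, where 8 splits called 15 or more (highest other 16), or for bcCML versus AML, where 40 called 8 or more (highest other 15).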

How the results depend on the processing

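The alternatives were planned before the data were examined. Counts of changed genes stayed within 1.5 times under DESeq2 size factors, library totals alone, no filter and haemoglobin genes left out. Beyond that, the counts for AML versus BM, bcCML versus BM and bcCML versus AML were 430, 101 and 179 with a test against a log2 fold change of 1, which asks for more by construction. With limma voom they were 8557 and 3220 for the first 2, with DESeq2 2289 and 2706 for the last 2. For bcCML versus AML the stricter filter, which tests fewer genes, gave 999 and a fit of these groups alone 339. Shared higher genes were 337 without a filter, 18 with the fold test, 1009 with limma voom, 956 with DESeq2 and 10 with BM split. Shared lower genes were 127 with the stricter filter, 33 with the fold test, 1495 with limma voom, 465 with DESeq2 and 29 with BM split. Lists called fell to 3, 6 and 0 with an estimated correlation, and for bcCML versus AML were 13 without a filter and 5 with limma voom. Apart from the fold test, the filter and the split, the cause was not tested.

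With each library left out in turn the changed genes numbered 2688 to 4568, 702 to 1487 and 1235 to 2116, shared genes 318 to 722 higher and 135 to 334 lower, and called lists 15 to 16, 12 to 17 and 7 to 12. Of 94 calls of named genes 60 were kept under every alternative but the fold test. Reversed were IER3 in bcCML versus AML (4.18; -0.48 with limma voom, -0.12 with DESeq2, -0.08 without bcCML replicate 2 and at most 4.62 with another library left out) and MKI67 in bcCML versus AML (-0.09; 1.86 with limma voom). IER3 rests on 1 library. MKI67 stood at 577 CPM in AML replicate 11 and at most 136 CPM in the other AML libraries. Such a library weighs more in a mean count than in a mean of log2 CPM, but the cause of the reversal was not tested.

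Replicate numbers do not pair the libraries. The correlation of deviations averaged 0.007 over 24 pairs with the same number (-0.204 to 0.248) and -0.001 over 233 others, and 4 libraries were closest to their own number. The replicate block gave 4132, 952 and 1455 changed genes, 378 shared higher and 369 shared lower ones, and 14, 14 and 9 lists; 12 named genes lost and 4 gained a call. Of 2-fold changes simulated with the same spread in every group 32% to 36% were recovered, which limits what these group sizes show. The shares for groups of unlike spread were not simulated. Depth limits genes with a few counts per group, such as LTF, EPB42 and CXCL12 in AML.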

Other observations

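The contrasts described here were chosen only after the values were seen, and no explanation was tested. The HOXA and HOXB genes, which set positional identity and are high in many leukaemias, fell apart among the AML libraries. Their score was between -1.74 and 0.51 in AML replicates 3, 8, 10 and 11, and between 3.42 and 4.85 in the other 7 AML libraries, while BM lay between 2.04 and 2.65. HOXA9 and MEIS1 had standard deviations of 3.86 and 3.47 log2 CPM in AML against 0.29 and 0.42 in BM (n = 11 and 7). MEIS1 did not follow this grouping. It was 0 and 0.107 CPM in AML replicates 3 and 8, but 67.1 and 112.5 CPM in AML replicates 10 and 11. The group means of the score were 2.52 in AML and 2.36 in BM (exact permutation, adjusted p = 0.867), so a comparison of means does not show this spread.

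The T cell receptor component CD3E was high in only a few libraries. In bcCML replicates 4 and 10 CD3E stood at 173 and 73.9 CPM and the early T cell protein CD7 at 127 and 87.0 CPM, with CD34 at 1310 and 717 CPM. These were the most alike libraries of bcCML (correlation of log2 CPM 0.966) and may not be independent. HLA-DRA, an MHC class II chain, was low there, at 14 and 54.9 CPM, against a median of 1190 CPM over all 28 libraries, but also low in AML replicate 6 (30.2 CPM) and bcCML replicate 8 (135 CPM). TRAC, the T cell receptor alpha constant gene, was 2.25 and 0.584 CPM in those libraries and highest in AML replicate 11, at 174 CPM. TRBC2, a T cell receptor beta constant gene, was 89 and 94.5 CPM there, but also 111 CPM in AML replicate 8, 92.1 and 90.9 CPM in bcCML replicates 2 and 9, and 16.9 to 39.3 CPM in BM. CD3D was 150 and 62.9 CPM in bcCML replicates 4 and 10, 95.2 CPM in bcCML replicate 2 and 58.3 CPM in AML replicate 8. CD7 was also high beside little CD3E in bcCML replicate 1 (164 and 0.52 CPM) and in AML replicate 3 (104 and 1.74 CPM), and was highest in AML replicate 8 (206 and 11.3 CPM).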
